A study of Danio rerio with 82 samples.

How the data were processed

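The series covers zebrafish (Danio rerio) gametes and embryos, and the 4 samples analysed here are poly(A) RNA-seq libraries of oocytes of stages I, II, III and IV, 1 library per stage. Files of the other samples were not analysed here. Per the labels' protocols, ovaries of adult females of the Tu strain were dissected, oocytes were sorted with tweezers by morphology, and follicle cells around them were removed as far as this was possible. Poly(A) RNA was selected on oligo(dT) beads, fragmented by heat, and copied into cDNA with oligo(dT) and random primers. The second strand was made with dUTP and removed with uracil-DNA glycosylase, so the libraries keep the strand of the transcript. Whether the quantification used strand is not given in the sources used here. Because selection is by the poly(A) tail, a transcript whose tail shortens can be lost from a library without being degraded.

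The authors deposited FPKM values per locus, with a lower and an upper FPKM confidence bound and a status, per the file headers. The column layout is that of a gene-level FPKM tracking table, and the quantification program is not given in the sources used here. The submitters' processing notes name Trim Galore, STAR 2.5.3a, Bowtie2 2.2.2, Bismark and the danRer7 genome build without a role for each, and they cover all assays of the series. Each file lists the same 28405 loci in a different order, so values were joined on symbol and locus. Of the 27564 symbols, 57.6% occur in a current zebrafish gene name table, and the symbols are printed as the files give them. The status was failed for 1 gene in stage I (zgc:153258) and 1 in stage IV (snrnp70). Starts in the files count from 0, since end minus start is a multiple of 3 for 10 of 13 mitochondrial protein genes and end minus start plus 1 for 0 of 13, and 1 was added to each start.

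No read counts were used. The bounds lie 2 FPKM/√n from the estimate where a value rests on n counted fragments, so each value was given the number of fragments that would produce its bounds by counting alone, here called fragment equivalents. Between 0.5 and 20 equivalents, 48.7%, 48.4%, 48.0% and 45.9% of the values of stages I to IV were within 0.02 of a whole number. Any error beyond counting widens the bounds and lowers the equivalents, so the sums over loci of 6260350, 6606980, 6572490 and 6201820 were taken as lower limits of the fragments used. For some abundant genes the equivalents did not follow the FPKM, as for actb1, with 2670, 2650 and 2663 equivalents at 4725, 1643 and 1953 FPKM in stages I to III, and the cause was not tested. A set of 3739 genes had at least 20 equivalents in each library and a ratio of equivalents to FPKM within 10% across libraries. In this set the ratio in stages II, III and IV was, at the median, 0.989, 0.986 and 1.00 times that in stage I. The genes were chosen for a stable ratio, so these values could differ by about 10% at most and do not show equal depth. FPKM sums were 772948, 708661, 805766 and 682092. An exact 0 is reported as listed at 0.

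Differences were taken on the log2(FPKM + 1) scale, which understates the change of low genes, among the 14109 loci with a mean of at least 1 FPKM over the 4 libraries. A gene was called higher or lower when the difference reached 1, a 2-fold change on this scale. With 1 library per stage there was no test, no SE and no p-value. The comparisons were stage IV against stage I and the 3 steps between successive stages. Under alternatives 2000 random lists were drawn. For values without replicates, a list median was held to have moved when it left the 95% bootstrap interval over members, a named gene when it left the range its bounds allow, and a correlation when it left its Fisher interval across genes. Genes past the stage IV against stage I rule were also sorted by whether their 3 steps went one way. Pearson and Spearman correlations across genes describe the similarity of libraries. For each of 23 gene lists the median difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list was said to stand apart when its percentile was at most 2.5 or at least 97.5. The percentiles describe these libraries. Random lists were not matched on transcript length. A symbol at several loci entered a list at the locus with the highest mean FPKM, and 1 gene, h1m, was a member of 2 lists. The lists cover germ plasm and piRNA genes, meiotic prophase, egg envelope, oocyte factors, maternal factors, histone acetylation, deacetylases, polycomb, H3K4 and H3K36 methyltransferases, DNA methylation, translational control, meiotic maturation, replication licensing, histone variants, yolk uptake, 4 groups of markers of other cell types, immediate early genes, ribosomal proteins, nuclear oxidative phosphorylation and mitochondrially encoded mRNAs.

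The groups, comparisons, lists, the rule for named genes and the alternatives, apart from those said to be added, were set before the data were examined. The rule takes, for stage IV against stage I, the 12 highest and 12 lowest genes with at least 10 FPKM in one of the 2 libraries and a symbol that is unique and no placeholder, the 5 highest and 5 lowest of each step by the same criteria, the 5 most abundant genes of each library, up to 4 members per list with the largest absolute stage IV against stage I difference, and all measured members of the maternal factor, oocyte factor and DNA methylation lists. Of the genes so named, 2 are not reported here; they stay in the counts and medians of their lists. The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 FPKM, rescaling each library to the same sum (TPM), median-of-ratios scaling, rescaling without the 50 most abundant genes, a 4-fold rule, non-overlapping bounds, and leaving out genes with failed status, of other cell types, or of mitochondria and ribosomes.

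The calculations were tested on simulated data in which fragment equivalents of the earlier library were redrawn and 200 of 14109 genes changed. The changed genes were drawn from those with at least 20 fragment equivalents in the earlier library. The shares of changed genes below therefore do not cover genes with fewer. For stage IV against stage I, 96% of genes changed 4-fold and 25% of genes changed exactly 2-fold reached the rule, since the pseudocount brings a 2-fold change in FPKM under it, and 108 of 13909 unchanged genes did. For stage II against stage I, the simulation called 136 of 13909 unchanged genes, for stage III against stage II 112, and for stage IV against stage III 96. Both simulated libraries were drawn with counting error only. Differences between pools of oocytes or between library preparations were left out, so these numbers do not give the rate of false calls in the data. Python with numpy, pandas, scipy and matplotlib was used, in the versions 3.11.15, 2.4.6, 2.3.3, 1.17.1 and 3.10.9.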

Results

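Zebrafish (Danio rerio) oocytes of the Tu wild-type strain were sorted by morphology from adult ovaries into successive growth stages, and polyadenylated RNA of stages I, II, III and IV was sequenced. The labels name the stage I cells as G1-phase, the stage II cells as S-phase, the stage III cells as prophase I and the stage IV cells as metaphase I oocytes. The cells were sorted by morphology, and these phases were not checked here. The 4 libraries analysed here, 1 per stage, belong to a series of 82 samples on chromatin and transcripts of gametes and embryos. The comparisons ask how the oocyte's stored transcripts differ between the stages of growth and maturation, with a closer look at the writers and readers of the chromatin marks that the series maps. Values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 28405 loci with 27564 distinct symbols, given by the authors with a lower and an upper confidence bound per locus. The widths of these bounds correspond to at least 6260350 fragments in stage I, 6606980 in stage II, 6572490 in stage III and 6201820 in stage IV. The bounds belong to single libraries, and which errors they cover is not given in the sources used here. With 1 library per stage no difference has a replicate check, so no p-value is given, and the words higher and lower describe these libraries. Coordinates are those of the danRer7 (Zv9) build, and exon and UTR annotation of that build was not used here.

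At 1 FPKM or more, 14063 genes were present in stage I, 13854 in stage II, 14536 in stage III and 11100 in stage IV. The median FPKM of the 14109 genes with a mean of at least 1 FPKM over the libraries was 12.4, 15.2, 13.1 and 5.98 in stages I to IV. Across these genes, which are not independent replicates, the log2(FPKM + 1) values of stages I and II had a Pearson correlation of 0.96 (Spearman 0.96), those of stages II and III 0.92 (0.92) and those of stages I and III 0.92 (0.91). Stage IV stood apart, with correlations of 0.71 (0.69) to stage I, 0.74 (0.74) to stage II and 0.71 (0.69) to stage III. The most abundant transcripts also differed. In stage I the highest FPKM belonged to rps20, crp2, phc2b, actb1 and si:ch73-132k15.2, with actb1, a cytoplasmic actin gene, at 4725 FPKM against 219 in stage IV. In stage II mt-atp8 and mt-co2 joined rps20, crp2 and phc2b among the highest, and in stage III mt-atp8, mt-co1 and MFAP4 (8 of 14) joined rps20 and crp2. In stage IV the highest were mt-atp8, rps20, phc2b, mt-atp6 and mt-co1. The value of rps20, 25433 (bounds 23062 to 27804) in stage I, has bounds as wide as those of 460 counted fragments.

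Stage IV was compared with stage I as the ends of the series. Transcripts of egg envelope and ribosomal proteins were lower in stage IV as lists, and so was the actin gene actb1. H3K4 and H3K36 methyltransferases were higher as a list, and higher single genes included the patterning factors pou5f3 and eomesa, dnmt1 and the cyclin gene ccne1. All 13 mitochondrially encoded mRNAs were also higher. Markers of follicle, stromal and blood cells were lower in most cases.

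By a log2(FPKM + 1) difference of at least 1, a 2-fold difference on this scale, 2689 genes were higher and 6260 lower in stage IV than in stage I. The lower genes were 70.0% of those past the rule. At 4-fold the numbers were 953 and 3145. The median difference over all 14109 genes was -0.75, and list medians below are therefore set against random lists matched on mean expression, given as percentiles among 10000 such lists. The number of lower genes was 3873 with a pseudocount of 5 and 3368 among genes with a mean of at least 10 FPKM. Without the genes at least 2-fold higher in stage III than in stage II, the step in which the lists of other cell types were higher, 2574 genes were higher and 5537 lower, an alternative added after the data were seen.

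**Figure D1:**
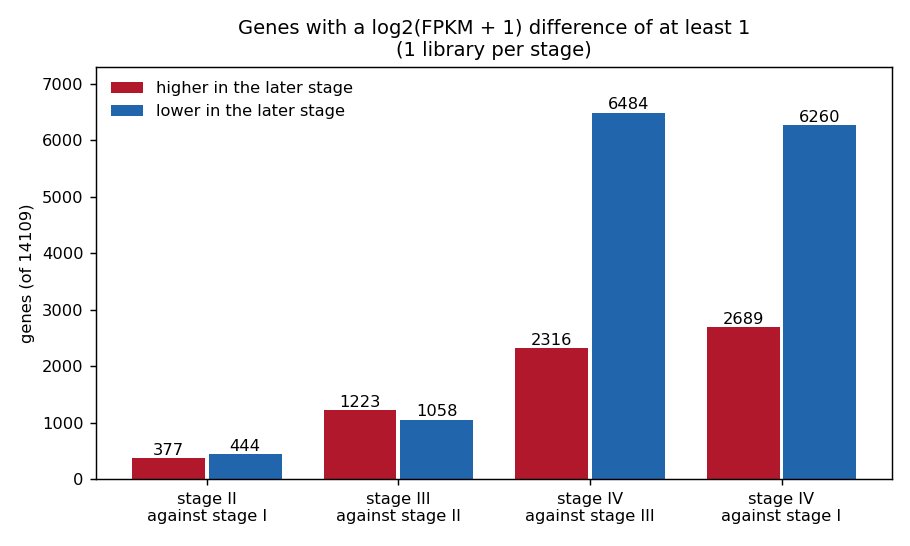
Number of genes (vertical axis) with a log2(FPKM + 1) difference of at least 1 in each comparison of 2 libraries, among 14109 genes, with red bars for genes higher and blue bars for genes lower in the later stage. The comparisons with stage IV hold 6484 and 6260 lower genes, against 444 and 1058 for the earlier steps.

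On the log2(FPKM + 1) scale, and among genes that the naming rule admits, fam101b lay furthest above its stage I level. The gene encodes a filamin-binding regulator (chromosome 15, 24449580 to 24453227). It was at 7.18 (bounds 5.89 to 8.47) FPKM in stage I and 481 (bounds 459 to 503) in stage IV, a log2 difference of 5.88. It was followed by papd7, a noncanonical poly(A) polymerase (chromosome 19, 28290859 to 28317020), at 4.82 (bounds 3.99 to 5.64) and 211 (bounds 201 to 221). The nuclear phosphoprotein gene nucks1a (chromosome 11, 39774685 to 39788284) was at 17.7 and 539 FPKM, and flii, an actin-binding protein gene (chromosome 3, 40200813 to 40227397), at 5.79 and 189. The log2 differences of shoc2, a scaffold of the RAS pathway, and of the activin receptor ACVR2B (1 of 2) were 4.68 and 4.66. AGO1, an Argonaute gene (chromosome 16, 54642280 to 54708191), was at 0.49 FPKM in stage I and 35.4 in stage IV. The RNA-binding protein gene khsrp was at 22.1 and 555 FPKM, PARD3B (2 of 3), a relative of a cell polarity gene, at 1.7 and 61.4, sfxn1, a mitochondrial carrier gene, at 1.05 and 45.4, and pcnt, which encodes the centrosome protein pericentrin, at 3.64 and 98. For runx2b, also among the 12 highest, the stage IV value of 65.2 (bounds 0 to 156) FPKM had a lower bound at 0. Its bounds therefore do not set stage IV apart from stage I.

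The lowest on the log2(FPKM + 1) scale, by the same rule, was ECM1 (2 of 2), an extracellular matrix gene (chromosome 19, 11893596 to 11896364). It was at 1230 (bounds 1191 to 1269) FPKM in stage I and 2.59 (bounds 0.759 to 4.42) in stage IV. MFAP4 (8 of 14) (chromosome 1, 59741975 to 59743179) was at 2286 and 16.3 FPKM and MFAP4 (12 of 14), from the same cluster, at 185 and 1.57. How the authors' quantification divided reads among the copies of this family is not given in the sources used here, so their single values are uncertain. The prothrombin gene f2 (chromosome 7, 40142973 to 40152260) was at 158 FPKM in stage I and 0.23 in stage IV. The smooth muscle gene tagln was at 130.3 and 0.192 FPKM, and the epithelial keratin gene krt18 at 121 and 0.291. The feedback inhibitor of cytokine signalling socs3a, the immediate early gene junba and icn had log2 differences of -6.14, -5.97 and -5.72. SMIM4 and mvdb, at 102 and 63.1 FPKM in stage I, were listed at 0 in stage IV. The remaining gene of the 12, AL928875.1, is a locus of very few bases (chromosome 5, 25800922 to 25801043) whose stage I bounds start at 0.

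The egg envelope genes encode the zona pellucida proteins that the growing oocyte deposits around itself. All 13 of 13 measured members were lower in stage IV than in stage I, with a median log2 difference of -4.76 (percentile 0). The gene zp3a.1 (chromosome 20, 34016409 to 34018306) was at 3105 (bounds 2978 to 3232) FPKM in stage I and 80.7 (bounds 74.1 to 87.3) in stage IV, zp2.2 at 482 and 12.4, zp2l1 at 1150 and 37.5, and zp2l2 at 113 and 2.96. These genes have close copies, and reads shared among them could be divided in more than 1 way. Of 10 measured oocyte transcription factors and growth factors, 8 were lower, 0 higher and 2 in between, with a median of -1.90 (percentile 5.02), which lies within the middle 95% of random lists, while with no filter the median was -0.92 and below it (percentile 0.9). The maternal effect gene zar1 (chromosome 20, 23411327 to 23413852) was at 836, 479.5, 159.8 and 21.7 FPKM in stages I to IV. The oocyte growth factors bmp15 and gdf9 were at 94.4 and 33.8 FPKM in stage I and at 13.1 and 8.99 in stage IV. The transcription factor genes lhx8a and nobox had log2 differences of -2.02 and -1.75, the nucleoplasmin genes npm2b and npm2a -2.18 and -1.06, and taf4b was at 11.4 and 2.1 FPKM. The importin gene kpna7, at 683 (bounds 671 to 696) and 694 (bounds 681 to 707) FPKM, differed by less than its bounds, and zar1l was at 1665 and 987.

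Of 22 germ plasm and piRNA pathway genes, 13 were lower and 4 higher in stage IV, with a median of -1.56 (percentile 2.67, within the middle 95%, but below it at percentile 1.7 with a pseudocount of 5 and 1.8 with no filter). The PIWI gene piwil1 (chromosome 8, 45837727 to 45912215) was at 88.7 FPKM in stage I and 7.15 in stage IV, asz1 at 92.7 and 7.01, and rbpms2b, which encodes an RNA-binding protein of the germ plasm, at 722 and 51.4. The piRNA methyltransferase gene henmt1 was at 56.1 FPKM in stage I and 2.56 (bounds 0 to 6.97) in stage IV. Of 14 meiotic prophase genes, 8 were lower and 3 higher, with a median of -1.13 (percentile 32.8, and -0.49 with no filter). The recombination genes mnd1 and psmc3ip, whose products form a complex, were at 37.1 and 38.4 FPKM in stage I and at 1.36 and 2.47 in stage IV. The synaptonemal complex gene sycp3 went the other way, from 2.33 (bounds 1.38 to 3.27) to 14.4 (bounds 11.5 to 17.4), while sycp2l had a log2 difference of -3.25.

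Among 19 maternal factors for genome activation and patterning, 7 were higher and 4 lower in stage IV, and the median was 0.67 (percentile 94.6, within the middle 95%, but above it at percentile 97.8 with no filter, and a median of 1.06 with median-of-ratios scaling). The pluripotency factor gene pou5f3 (chromosome 21, 11887950 to 11892809) was at 24.7, 14.8, 8.61 and 203 FPKM in stages I to IV, with stage IV bounds from 198 to 209. The T-box gene eomesa (chromosome 19, 839729 to 853794) was at 38.9, 50.5, 16.4 and 217. The orphan receptor gene nr6a1a was at 15 (bounds 5.96 to 24.1) and 81.7 (bounds 60.1 to 103), lnx2b at 74 and 361, and ctnnb2, a beta-catenin gene of dorsal axis formation, at 145 and 619.5. The scaffold gene grip2a and the Nodal effector gene smad2 had log2 differences of 1.74 and 1.12. The homeobox gene nanog was at 401, 376, 211 and 638 FPKM, a stage IV against stage I difference of 0.67 that did not reach the 2-fold rule. Differences under the rule were also found for ctnnb1 (0.86), sybu (0.76), zfyve26 (0.66), dvr1 (0.16), mid1ip1l (0.08), foxh1 (-0.69) and sox19b (-0.77). The 4 lower genes were mych, at 46.7 and 1.44 FPKM, ctcf, at 29.7 (bounds 21.9 to 37.5) and 7.11 (bounds 1.6 to 12.6), vsx1, at 1.8 and 0.0598, and wnt8a, at 44.6 and 18.5.

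**Figure D2:**
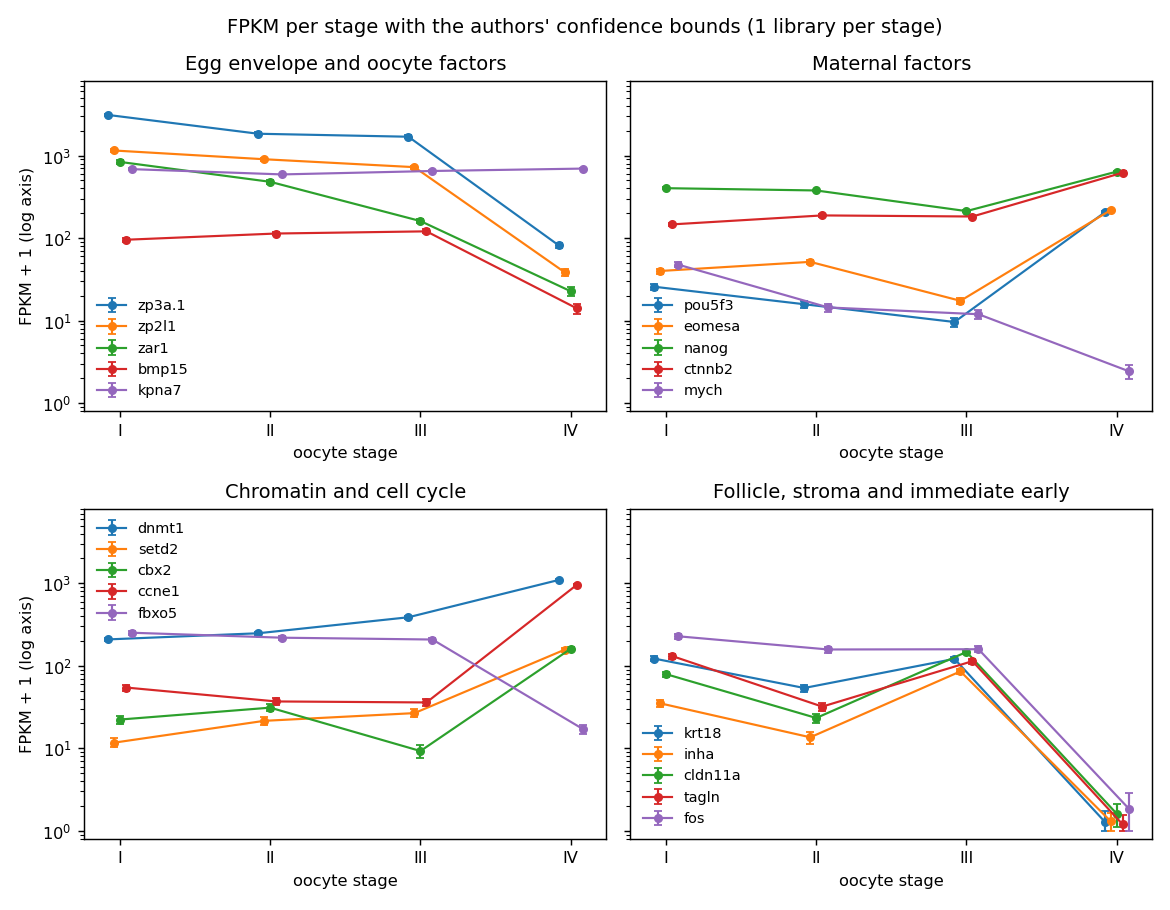
FPKM + 1 (vertical axis, log scale) of 20 genes in the libraries of oocyte stages I to IV (horizontal axis), 1 library per stage, with bars for the authors' confidence bounds and a panel for each group of genes. From stage III to stage IV zp3a.1 goes from 1690 to 80.7 FPKM, pou5f3 from 8.61 to 203 and krt18 from 120.2 to 0.291.

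The methyltransferases of H3K4 and H3K36 stood above matched random lists, with 8 of 18 measured members higher and 2 lower in stage IV and a median of 0.89 (percentile 99.87). The H3K36 methyltransferase gene setd2 (chromosome 16, 18304489 to 18354237) was at 10.7 (bounds 9.24 to 12.1) FPKM in stage I and 156 (bounds 148 to 163) in stage IV. The H3K4 methyltransferase gene kmt2ba (chromosome 19, 9855212 to 9897776) was at 8.53 and 58.1, whsc1 at 26 and 128, and cxxc1l, a CpG-binding subunit of H3K4 methyltransferase complexes, at 16.4 and 58.5. Histone acetylation writers and readers split by gene, with 4 higher and 5 lower of 16 (median 0.21, percentile 93.9, and a median of -0.03 with no filter and 0.55 with median-of-ratios scaling). The acetyltransferase gene ep300b was at 4.84 and 29.9 FPKM, while the bromodomain gene brd2a was at 94.8 and 5.46 and crebbpa at 10.6 and 0.831. Of 19 histone deacetylases and their corepressors, 7 were higher and 8 lower (median -0.77, percentile 54, and -0.31 with a pseudocount of 5), with hdac1 at 146 and 542 FPKM, the SIN3 corepressor genes sin3ab and sin3aa at log2 differences of 1.97 and 1.89, and sirt6 at -2.12.

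Of 27 polycomb complex genes, 4 were higher and 13 lower in stage IV, with a median of -0.96 (percentile 26.4). The chromobox gene cbx2 (chromosome 3, 10535521 to 10548188) was at 21.3, 30.1, 8.26 and 159 FPKM in stages I to IV. Lower members included phc2a, at 102 and 15.2, rbb4l, at 48.3 and 9.17, and cbx8b, at 26.4 and 4.66. In the DNA methylation list 2 genes were higher and 5 lower of 11 (median -0.75, percentile 49.8, and -1.25 and -0.39 with pseudocounts of 0.1 and 5). The maintenance methyltransferase gene dnmt1 (chromosome 3, 55442890 to 55458859) was higher at each stage, at 208, 247, 386 and 1095 FPKM, with bounds of 199 to 217 in stage I and 1052 to 1137 in stage IV. The methyl-CpG-binding domain gene mbd3a was at 58.4 and 131 FPKM and mbd3b at 7.27 and 3.01. Of the other DNA methyltransferase genes, dnmt5 was at 24 and 34.6, dnmt4 at 5.38 and 2.95 and dnmt3 at 15.1 and 5.06. The values of tdg, gadd45aa and gadd45ab differed by -1.42, -1.20 and -1.14 on the log2 scale, and that of mbd2 by -0.47. Histone variants went both ways, 3 higher and 4 lower of 8 (median -0.62, percentile 54.1, and a median of 0 with no filter). The variant gene h2afx was at 340.4 and 18.8 FPKM, the linker histone gene h1f0 at 9.09 and 0.26 and h1fx at 6.13 and 0.80, while the H2A.Z gene h2afvb was at 354 and 1225.

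Meiotic maturation genes and cyclins had 13 higher and 8 lower members of 31 (median 0.39, percentile 92.5, and 0.77 with median-of-ratios scaling). Cyclin E gene ccne1 (chromosome 7, 47629355 to 47639396) was at 53.5 (bounds 49.1 to 57.9) FPKM in stage I and 953 (bounds 917 to 988) in stage IV, and the separase gene espl1 at 15.1 and 261. The anaphase-promoting complex regulators fbxo5, an inhibitor, and fzr1, an activator, were at 250.3 and 42.8 FPKM in stage I and at 16.2 and 1.45 in stage IV. DNA replication licensing genes had 10 higher and 11 lower members of 34 (median 0.12, percentile 77.2, and 0.05 with no filter to 0.50 with median-of-ratios scaling). The loading factor gene cdc6 was at 108 and 713 FPKM, while mcm3l was at 146 and 5.13, mcm5 at 98.7 and 7.26 and orc3 at 93.1 and 7.67. In translational control and mRNA decay 7 genes were higher and 15 lower of 28 (median -1.27, percentile 9.45). The poly(A)-binding protein gene pabpc1l was at 282 and 6.2 FPKM, lsm14b at 414 and 40.9, and the m6A reader gene ythdf1 at 30.4 and 1.65. The deadenylase subunit gene pan3 was at 12.3 and 174. Of 20 yolk uptake and processing genes 3 were higher and 9 lower (median -0.59, percentile 41.1, and -0.15 with no filter). The endocytic adaptor gene dab2 was at 295 and 10.9 FPKM, the lipoprotein receptor gene vldlr at 189 and 13.6, the clathrin gene cltcb at 24.9 and 1.88 and rbp4 at 16.7 and 0.488.

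Cytosolic ribosomal protein genes were lower in 58 of 76 cases and higher in 0 (median -1.28, percentile 1.05). Their share of the summed FPKM was 11.4% in stage I and 5.72% in stage IV. Within these shares rps20 alone held 3.29% of the summed FPKM in stage I and 2.05% in stage IV. The genes rpl35a, rplp0, rpl19 and rpl13a had log2 differences of -3.38, -3.03, -2.69 and -2.55. Nuclear genes of oxidative phosphorylation were lower in 49 and higher in 2 of 85 cases (median -1.32, percentile 0.03). The largest differences in that list were those of ndufab1b, at 57.4 and 2.44 FPKM, cox7a3, at 222 and 16.4, ndufs8b, at 29.7 and 1.5, and sdhdb, at 103 and 7.83. The 13 mitochondrially encoded mRNAs were all higher, with a median of 2.13 (percentile 100), and their share of the summed FPKM was 1.84%, 4.89%, 9.14% and 8.78% in stages I to IV. The subunit genes mt-nd5 and mt-nd2 were at 199 and 242 FPKM in stage I and at 1259 and 1427 in stage IV, and mt-atp6 and mt-atp8 had log2 differences of 2.66 and 2.46.

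The surrounding follicle cells had been removed as far as possible, and lists of markers of other cell types were measured in each library. Follicle somatic markers were lower in stage IV than in stage I in 17 of 22 cases (median -2.76, percentile 0), and their share of the summed FPKM was 0.11% in stage I, 0.08% in stage II, 0.15% in stage III and 0.03% in stage IV. The list members cyp11a1 and cyp17a1, chosen after their values were seen, were at 224, 138, 205 and 170.5 and 74.7, 55.9, 55.4 and 33.8 FPKM over the stages, and without them the shares were 0.0715%, 0.0524%, 0.118% and 0.0022%. The tight junction gene cldn11a was at 78.2, 22.3, 146 and 0.61 FPKM in stages I to IV, the inhibin gene inha at 34.1, 12.6, 84.5 and 0.305 and the keratin gene krt8 at 130.4, 61.7, 152 and 1.83. Stromal and endothelial markers were lower in 19 of 21 cases (median -2.32, percentile 0), with acta2, fn1b and pdgfrb at 80.4, 32.7 and 20.8 FPKM in stage I and at 0.703, 0.577 and 0.055 in stage IV. Blood and immune markers were lower in 15 of 18 cases (median -2.04, percentile 0.09), including the invariant chain genes cd74a, at 64.6 and 1.42 FPKM, and cd74b, at 39.3 and 3.23, the leukocyte gene lcp1, at 6.28 and 0.077, and the globin gene hbaa1, at 20.7 and 2.2. With no filter the follicle median was -1.13 (percentile 1.85). All 11 measured liver and yolk protein genes were lower (median -2.47, percentile 0), with tfa and hp at 8.18 and 5.49 FPKM in stage I and listed at 0 in stage IV. These are 11 of 28 genes in the list, and with no filter the median was -0.91. The sizes of these medians depend on the pseudocount: with 0.1 and 5 they were -4.26 and -1.30 for follicle, -4.33 and -0.92 for stromal, -3.52 and -0.96 for blood and -3.88 and -1.07 for liver and yolk genes, each below its random lists. Immediate early and dissociation stress genes were lower in 18 and higher in 1 of 22 cases (median -2.42, percentile 0.01, and -4.85 and -1.78 with pseudocounts of 0.1 and 5), with fos at 227, 157, 158 and 0.861 FPKM, egr1 at 57.8 and 0.312 and junbb at 65.6 and 0.352. The higher one was dusp1, at 145 and 771, and the list's share of the summed FPKM was 0.176% in stage I and 0.219% in stage IV. In stage IV 5 follicle, 4 stromal and 7 blood markers were still at 1 FPKM or more.

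**Figure D3:**
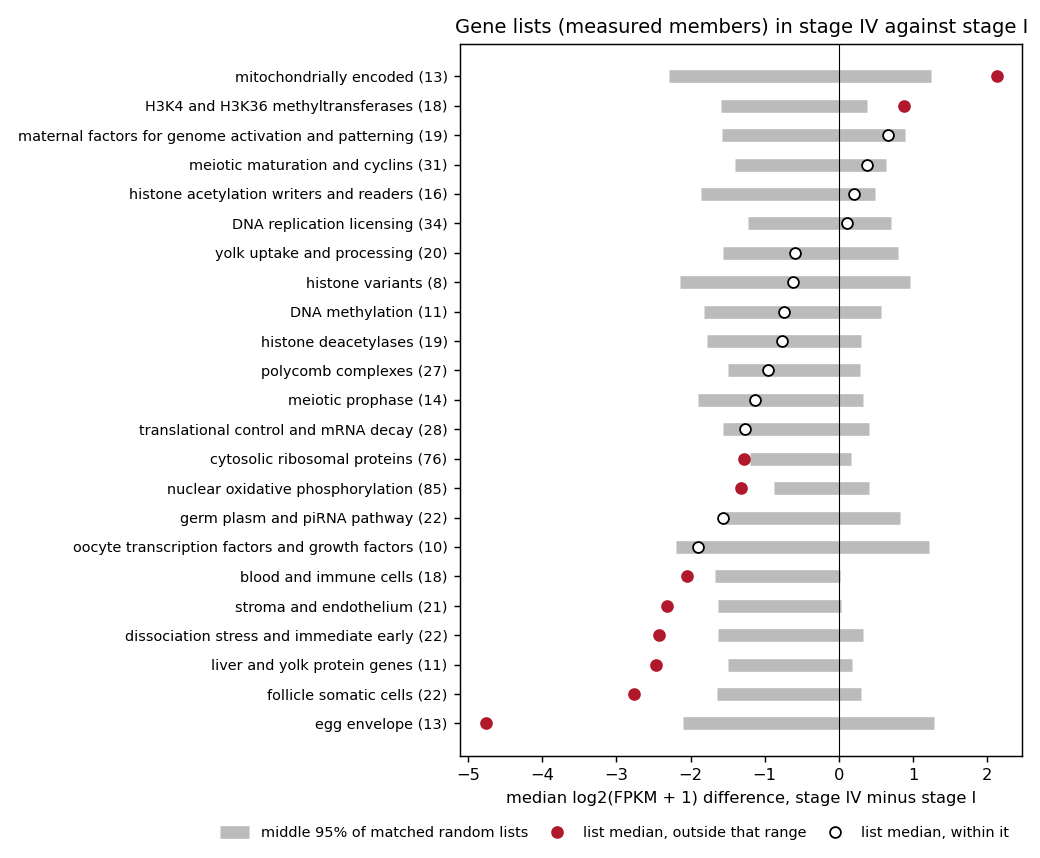
Median log2(FPKM + 1) difference of stage IV minus stage I (horizontal axis) for 23 gene lists, with the number of measured members in parentheses, as points over grey bars that span the middle 95% of 10000 random lists matched on mean expression. The egg envelope list lies lowest at -4.76 and the mitochondrially encoded list highest at 2.13, and 2 lists lie above and 8 below their random lists.

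The comparison of stage II with stage I asked what differs at the start of oocyte growth. Stage II held more of the mitochondrially encoded mRNAs. The medians of the ribosomal protein, egg envelope and stromal lists lay below random lists, although few of their members passed the 2-fold rule. The yolk and clotting protein genes vtg1 and f2 were also lower. By the 2-fold rule 377 genes were higher and 444 lower in stage II, with a median difference of 0.20 over all genes. The yolk precursor gene vtg1 was at 22.6 (bounds 20.1 to 25) FPKM in stage I and listed at 0 in stage II, the urea transporter gene slc14a2 was at 12.5 FPKM in stage I and listed at 0 in the other libraries, and f2 was at 158 and 9.99 FPKM. The mitochondrially encoded list had 10 of 13 members higher (median 1.29, percentile 100) and the histone deacetylases a median of 0.47 (percentile 98.11) with 0 of 19 past the rule. Liver and yolk protein genes had 8 of 11 lower (median -2.39, percentile 0). The list holds 28 genes, and its median was -0.38 with no filter, -5.44 with a pseudocount of 0.1 and -0.89 with one of 5, each below random lists. Ribosomal protein genes had a median of -0.46 (percentile 0), egg envelope genes -0.53 (0.2), stromal markers -0.49 (0), follicle markers -0.20 (0.02), blood markers -0.32 (0.08) and immediate early genes -0.47 (0). Lower by the rule were 5 of 76 ribosomal protein genes, 0 of 13 egg envelope genes, 5 of 21 stromal, 5 of 22 follicle and 3 of 18 blood markers and 1 of 22 immediate early genes, and 3 follicle markers were higher. The follicle median was -0.06 with a pseudocount of 5 and -0.05 with no filter. The remaining lists below random lists were meiotic prophase (-0.07, 1.44), germ plasm (-0.05, 0.64) and nuclear oxidative phosphorylation (-0.04, 0.17), whose medians were 0.03, 0.07 and 0.08 after rescaling each library to the same sum (TPM) and each -0.28 with median-of-ratios scaling. That scaling gave 0.24 for the deacetylases, -0.69 for ribosomal protein genes and -0.52 for blood markers, and a pseudocount of 5 gave -0.26 for stromal markers, -0.21 for blood markers and -0.29 for immediate early genes. With no filter the meiotic prophase list lay within its random lists, at percentile 4.2. The histone deacetylase list lay within its random lists with a pseudocount of 5, at percentile 94. The highest genes by rule were fgf2, plek, CABZ01087562.1, clasp1a and usp24. They rest on at most 22 fragment equivalents in stage II, and the stage II value of fgf2, 17.1 (bounds 1.81 to 32.4) FPKM, has bounds as wide as those of 5 counted fragments. The lowest also included agtpbp1 and AL928875.1, whose stage I bounds start at 0. The split of calls depended on scaling, with 54.1% of the genes past the rule lower as deposited, 36.6% (409 lower, 707 higher) after rescaling to TPM, 79.5% (678 and 175) after median-of-ratios scaling and 38.9% (360 and 566) without mitochondrial and ribosomal genes. Over 3681 genes whose bounds allowed a length proxy, the stage II against stage I difference had a Spearman correlation of 0.30 across genes with that proxy, the fragment equivalents per FPKM, and that of stage III against stage II -0.24.

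The comparison of stage III with stage II asked what differs as growth goes on. Stage III held more follicle, stromal and blood cell transcripts than stage II and again more mitochondrially encoded mRNAs, and less of germ plasm, polycomb, histone acetylation and translational control transcripts as lists. Higher by the rule were 1223 genes and lower 1058, with a median difference of -0.10 over all genes. The hydroxylase gene cmah (chromosome 4, 2091681 to 2111243) was at 7.57 FPKM in stage II and 223 in stage III, CABZ01064405.1 at 1.56 and 179.6, rprmb at 0.696 and 41.7 and asb11 at 4.09 and 93.1. AL928875.1, also among the 5 highest, had stage III bounds that start at 0. Follicle markers were higher in 12 and lower in 1 of 22 cases (median 1.23, percentile 100), stromal markers higher in 10 of 21 (median 0.94, percentile 100) and blood markers in 10 of 18 (median 1.32, percentile 100). With no filter the follicle and blood medians were 0.57 and 0.85, and with a pseudocount of 5 the stromal and blood medians were 0.46 and 0.78, each above random lists. Mitochondrially encoded mRNAs had 10 of 13 higher (median 1.2, percentile 100). Ribosomal protein genes had a median of 0.65 (percentile 100), nuclear oxidative phosphorylation genes 0.42 (100) and yolk uptake genes 0.40 (99.96; 0.20 with no filter), with 1 of 76, 6 of 85 and 2 of 20 members higher by the rule. After rescaling to TPM the last 2 medians were 0.24 and 0.23. Below random lists lay the germ plasm list at -0.69 (percentile 0.01), histone acetylation at -0.75 (0.04), polycomb at -0.53 (0.16) and translational control at -0.44 (0.08), with 7 of 22, 3 of 16, 5 of 27 and 5 of 28 members lower by the rule. Translational control was at -0.28 with median-of-ratios scaling. In the same step zar1 differed by -1.58 on the log2 scale, eomesa by -1.57 and cbx2 by -1.75, and gdf9 was at 39.7 and 13.4 FPKM. The lowest genes by rule were SMIM13 (2 of 2), C7 (2 of 2), b3galtlb, pik3ap1 and chrnb3b. SMIM13 (2 of 2), at 49.7 FPKM in stage II and 210.3 in stage IV, and b3galtlb, at 12.8 and 14.6, were listed at 0 in stage III, and C7 (2 of 2) was at 0.0686 between 32.5 and 22. Of the genes past the rule 46.4% were lower as deposited, 62.8% (1839 lower, 1090 higher) after rescaling to TPM and 30.6% (638 and 1445) with median-of-ratios scaling, so which direction prevailed in this step depended on scaling. The differences of this step and of stage II against stage I had opposite correlations with the length proxy (-0.24 and 0.30), and random lists were not matched on length. Several list medians had opposite signs in the earlier and the later of these steps. Among them were ribosomal protein genes (-0.46 and 0.65), nuclear oxidative phosphorylation (-0.04 and 0.42), histone acetylation (0.43 and -0.75) and polycomb genes (0.32 and -0.53). Others were follicle (-0.20 and 1.23), stromal (-0.49 and 0.94) and blood markers (-0.32 and 1.32) and histone deacetylases (0.47 and -0.39). How far such shifts follow transcript length was not tested.

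The comparison of stage IV with stage III asked what differs between the oocytes labelled as prophase I and as metaphase I. It held more genes past the rule than the earlier steps. Egg envelope genes and most somatic cell markers were lower, and maturation and cyclin genes and H3K4 and H3K36 methyltransferases were higher as lists, as were the single genes pou5f3, eomesa and cbx2. By the rule 2316 genes were higher and 6484 lower, or 73.7% lower among those past it, with a median difference of -0.82. With median-of-ratios scaling 3243 were higher and 5493 lower, or 62.9%. Of 7972 genes at 10 FPKM or more in stage III, 548 were under 1 FPKM in stage IV, while 31 genes under 1 FPKM in stage III were at 10 or more in stage IV. The highest genes were SMIM13 (2 of 2), papd7, at 2.26 and 211 FPKM, fam101b, at 8.82 and 481, the serine protease gene tmprss4a, at 11 and 420.3, and agtpbp1, at 3.23 and 130.4 (bounds 35.2 to 226). The lowest were MFAP4 (8 of 14), at 15587 and 16.3 FPKM, MFAP4 (12 of 14), at 1264 and 1.57, the collagenase gene mmp13a, at 771 and 0.89, the apolipoprotein gene apoeb, at 531 and 0.621, and ECM1 (2 of 2), at 1104 and 2.59.

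In this step 17 maturation and cyclin genes were higher and 10 lower of 31 (median 1.23, percentile 99.99, and 0.45 at percentile 98.1 with no filter), and 8 H3K4 and H3K36 methyltransferase genes were higher and 1 lower of 18 (median 0.78, percentile 99.9). Maternal factors had 8 higher and 3 lower (median 0.69, percentile 97.05, within the middle 95%, but above it at percentile 97.6 after rescaling to TPM or without the 50 most abundant genes, 97.8 with median-of-ratios scaling (median 1.15) and 98.2 with no filter), with log2 differences of 4.41 for pou5f3, 4.00 for nr6a1a and 3.65 for eomesa. All 13 egg envelope genes were lower (median -4.17, percentile 0), as were 19 of 22 follicle markers (median -3.75, percentile 0), 18 of 21 stromal markers (-2.50, 0.01) and 17 of 18 blood markers (-2.83, 0). The follicle, stromal and blood medians were -6.46, -4.43 and -4.18 with a pseudocount of 0.1 and -1.91, -0.98 and -1.51 with one of 5. Immediate early genes had 18 of 22 lower (-2.26, 0.04, and -4.30 and -1.19 with pseudocounts of 0.1 and 5). The other 4, dusp1, btg2, dnajb1a and dnajb1b, were higher, and the list's share of the summed FPKM was 0.126% in stage III and 0.219% in stage IV. These genes, and dusp1 above, were named after their values were seen. Nuclear oxidative phosphorylation genes were lower in 60 of 85 cases (-1.67, 0) and ribosomal protein genes in 63 of 76 (-1.43, 0.79). The 13 mitochondrially encoded mRNAs had 0 higher and 0 lower by the rule, with a median of -0.52 (percentile 55.2, and -0.06 with median-of-ratios scaling). DNA replication licensing genes had a median of -0.16 (percentile 64.6), which was 0.07 after rescaling to TPM and 0.29 with median-of-ratios scaling.

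Most of the genes that separated stage IV from stage I were similar in the first 3 stages. Of the 2689 genes higher in stage IV than in stage I, 2134 stayed within a 2-fold range over stages I to III. Of the 6260 lower genes 4391 did. Among all 14109 genes, 5.82% passed the rule in stage II against stage I and 16.2% in stage III against stage II. The share of all genes within the 2-fold range was not computed, so the range is not shown to set these genes apart. All 3 steps went one way for 1017 of the higher genes (37.8%), among them dnmt1, espl1, flii and setd2, and for 1141 of the lower genes (18.2%), among them zar1, mych, h2afx, piwil1 and zp2.2. The share that follows by chance among genes already chosen for their stage IV value was not computed. Most genes past the rule stayed within a 2-fold range over stages I to III, so small differences between single libraries can set the order there. These shares therefore do not show an ordered change.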

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

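No paired analysis was possible because there was 1 library per stage and no test. The alternatives with at least 10 fragment equivalents, without the genes higher in stage III than in stage II, with stage II or the mean of stages I to III as the reference, and for lists without the 50 most abundant genes were chosen after the data were seen. In the comparisons with stage IV no list outside its random lists, and for stage IV against stage I no named gene past the 2-fold rule, changed sign under the pseudocounts and scalings run. In stage II against stage I, where the medians lay near 0, 3 lists below their random lists did: after rescaling to TPM the germ plasm median was 0.07, meiotic prophase 0.03 and nuclear oxidative phosphorylation 0.08, and without the 50 most abundant genes the last was 0.01. Lists within their random lists as deposited left them in some settings: with no filter the H3K4 and H3K36 methyltransferases (percentile 98.7, and 98.1 with a pseudocount of 0.1) and the oocyte factors (0.65) in stage II against stage I, and the histone variants (98.1) in stage III against stage II, while the maturation and cyclin genes in stage III against stage II (2.56 as deposited, 3.75 with no filter) lay below theirs with pseudocounts of 0.1 (2.2) and 5 (1.15), after rescaling to TPM (1.85), with median-of-ratios scaling (2.25) and without the 50 most abundant genes (1.9). Over all 4 comparisons 71 list medians moved, 4 reversed and 477 did not move. Named genes were checked for stage IV against stage I only, where 273 values moved and 557 did not. Their differences in the 3 steps were not checked in this way. Reversed means a change of sign and was counted only for lists outside their random lists as deposited. Sign changes of other lists were counted as moved or not moved. An example is replication licensing in stage IV against stage III, at -0.16 as deposited and 0.29 with median-of-ratios scaling. The excess of lower genes in both comparisons with stage IV held under each alternative run. Some alternatives removed few genes. Of the 6484 genes lower in stage IV than in stage III, 6483 stayed without failed status and 6427 without the lists of other cell types. The latter setting does not address somatic transcripts outside those lists. Replicate spread is the limit that no alternative addresses, and genes on few fragments are limited by depth. Where counts moved with a stricter rule or filter, fewer genes could pass; for the scalings and pseudocounts the cause was not tested. With a pseudocount of 0.1, 746 genes were higher and 720 lower in stage II than in stage I. With a pseudocount of 5, 1 list in place of 2 lay above its random lists in stage II against stage I, and the numbers were 64 and 172 for stage II against stage I, 494 and 365 for stage III against stage II, 4096 lower for stage IV against stage III and 3873 lower for stage IV against stage I. Among genes with a mean of at least 10 FPKM they were 140 and 130, 303 and 580, 3414 lower and 3368 lower in the same order, with 618 ordered falling genes. Rescaled to TPM, 707 genes were higher in stage II than in stage I and 1839 lower in stage III than in stage II. Median-of-ratios scaling gave 175 higher and 678 lower genes for stage II against stage I and 638 lower for stage III against stage II. The 4-fold rule gave 22 and 86, 264 and 58, 711 and 3370, and 953 and 3145 genes for the 3 steps and stage IV against stage I, and 401 rising and 758 falling ordered genes. Without mitochondrial and ribosomal genes 566 genes were higher in stage II than in stage I, and without the genes higher in stage III than in stage II 267 were lower. That filter uses the stage II and III libraries themselves, so in the steps that share one of them it removes lower genes by construction. The correlations of stages I and II, II and III, III and IV, and I and IV were 0.943, 0.893, 0.669 and 0.687 with a pseudocount of 0.1 and 0.983, 0.967, 0.847 and 0.847 with no filter. With a pseudocount of 5 the first 3 were 0.971, 0.939 and 0.723, and median-of-ratios scaling gave 0.963 for stages I and II. The correlations with stage IV were the lowest in each of these settings.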

Other observations

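The tests below on the egg envelope, on fragments, on transcript length and on long mitochondrial genes were chosen after the result was seen. Genes far lower in a single library were counted for each stage. At least 10 FPKM in 3 libraries and under 10% of the lowest of these in the remaining one was found for 0 genes in stage I, 1 in stage II, 8 in stage III and 772 in stage IV. These counts are not comparable. Stage IV ends the series, so its count includes the lower genes reported above. A low value in stages I to III counted only with at least 10 FPKM in stage IV, which 5825 genes reached. The 8 genes of stage III include SMIM13 (2 of 2), at 16.6, 49.7, 0 and 210.3 FPKM over the stages, and C7 (2 of 2), at 25.7, 32.5, 0.0686 and 22.

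Gene pairs named with the suffixes a and b had partly similar differences between stage IV and stage I. Zebrafish carry many gene pairs from the genome duplication of teleost fish, which the nomenclature often marks with the suffixes a and b. Pairs were taken by these suffixes alone, so they can include genes that are not duplicates of this kind. Across 916 pairs the stage IV against stage I differences had a correlation of 0.29, above 10000 random re-pairings whose middle 95% ran from -0.07 to 0.07. The re-pairings were not matched on mean expression, so they do not separate a shared response from similar expression of the members. In 258 pairs both members passed the 2-fold rule in one direction, and in 110 they passed it in opposite directions, where 161 opposite pairs follow from the margins. Reads shared between close copies could give the same sign, which was not tested. The corepressor genes sin3aa (1.89) and sin3ab (1.97) went one way, and mbd3a (1.15) and mbd3b (-1.05) opposite ways.

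Neighbouring genes shared little. Over 6660 non-overlapping neighbouring pairs, taking every other pair, the same differences had a correlation of 0.0645, above random re-pairings (middle 95% -0.02 to 0.02), and over 3709 pairs at least 10000 bases apart it was 0.05. Neighbouring copies of one gene family were not left out, so a local component is not shown, and genes are not independent replicates.

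The excess of lower genes in stage IV over stage III was weighed against technical explanations. A shallower stage IV library would spare well-covered genes. Of 9124 genes with at least 100 fragment equivalents in stage III, however, 46.9% were lower by 2-fold or more. After rescaling without the 50 most abundant genes, ranked by mean FPKM over the 4 libraries, there were 2.44 lower genes per higher gene. This argues against those 50 genes as the whole cause. With median-of-ratios scaling 5493 genes were lower and 3243 higher, so the size of the excess depended on scaling. Loss of long transcripts would give a negative correlation with the length proxy, and rho was 0.0824 across 3681 genes. These genes had at least 20 fragment equivalents in each library, stage IV included. Transcripts lost from stage IV could not enter this set, so the test cannot exclude a loss of long transcripts. For the egg envelope list alone, whose genes the oocyte itself expresses, fewer somatic cells in stage IV would leave the share as it is or higher, and the median was -4.17. This does not bear on the excess of lower genes as a whole, for which the part due to somatic cells stays open. Loss or gain of poly(A) tails at maturation, which would move transcripts in or out of a poly(A)-selected library, degradation, and a difference between single libraries all stay open as untested.

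The follicle, stroma and blood lists lay below random lists in stage IV against stage III and above them in stage III against stage II. The stage III against stage II differences of 18 follicle markers with at least 20 fragment equivalents in both libraries ran from -1.79 for gsdf to 3.21 for hsd3b1, a steroidogenic enzyme gene, the ends of the range and so named after their values were seen. With 1 library per stage, the number of somatic cells in each library and the makeup or activity of the follicle cells at each stage both stay open.

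Mitochondrially encoded mRNAs and nuclear genes of oxidative phosphorylation lay on opposite sides of 0 in stage IV against stage I, with medians of 2.13 and -1.32. They did not in each step: the medians were 1.29 and -0.04 for stage II against stage I, 1.2 and 0.42 for stage III against stage II and -0.52 and -1.67 for stage IV against stage III. Under the 3 other scalings the stage IV against stage I medians were 2.24 to 2.52 and -1.22 to -0.96. The 6 mitochondrial genes with loci over 900 bases had a median difference of 2.26, against inflated FPKM of short transcripts as the whole cause. Scaling, changes in the amount of RNA and in poly(A) tails, and differences between single libraries stay open.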
